A study of Mus musculus with 16 samples.

How the data were processed

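Skeletal muscle RNA from male wild-type (WT) mice and mice lacking the cannabinoid 1 receptor in skeletal muscle (CB1KO), each fed a standard diet (SD) or one rich in fat and sugar (HFHS), was profiled on 16 one-colour Agilent arrays, 4 per group. Groups were taken from the sample titles, which match the source names, the descriptions and the series design. The diet tag among the sample characteristics differs from the titles for the CB1KO_SD and WT_HFHS arrays, and the titles were followed. The labels do not say which muscle was dissected. The growth protocol lists both genotypes as Cre-positive, so the genotype was taken from the titles as well.

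Per the file headers, the deposited scanner files were made with Feature Extraction 11.5.1.1 and hold spot intensities: a processed intensity, corrected for background within the array and not scaled between arrays, and the raw median intensity of each spot and its surroundings. The deposited series table holds a score per spot. Checked against the scanner files, it equalled each array's log2 processed intensity minus its mean over all spots and divided by its SD, to within 0.005. Each array had 62976 spots, of which 59305 were not controls, measuring 55681 probes. Of these probes, 28026 took a current symbol from a RefSeq gene table through the accession in the array file, and 27655 kept the identifier in the file. The array grid and the gene table use different genome builds, so no coordinates are given and only the order of genes along chromosomes was used.

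The log2 processed intensity minus each array's 75th percentile was analysed. Spots that Feature Extraction marked as outliers were set to missing (0.018% of the tested values), and repeated spots were averaged. Probes well above background on at least 4 of the 16 arrays were kept, and the brightest probe stood for each gene, which left 28964 genes. A linear model with 1 mean per group was fitted to all 16 arrays in R 4.3.3 with limma 3.58.1 (lmFit and eBayes). The contrasts were CB1KO against WT on each diet and averaged over both, the genotype-by-diet interaction, and HFHS against SD within each genotype. Adjusted p values are Benjamini-Hochberg values over all genes tested, with a threshold of 0.05, and tests were two-sided. Where a gene stood well above background on none of a group's arrays, the fold change is given as an approximate lower bound. For it, lower values in that group were raised to the array's lowest intensity called well above background. This level ran from -5.14 to -2.59 across arrays (log2, relative to the 75th percentile). A gene not well above background may truly lie above it, so the bounds are not strict. Single values of Cnr1, Il6 and Mstn were also compared by exact permutation tests, whose smallest possible p with 4 arrays against 4 is 0.0286.

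A set of 37 gene lists, covering muscle fibre types, metabolism, signalling, stress, immune genes and markers of other cell types in muscle, was tested with camera at its preset correlation of 0.01, and beside it with camera at an estimated correlation and with fry. List shifts are medians relative to the median of all genes. Of 782 list entries, 772 were on the array. The lists, comparisons, tests and alternatives were fixed before the data were examined, except those stated below to have been chosen later. The rule for the genes named was fixed then too: Cnr1, Il6 and Mstn always, in each comparison up to 10 higher and 10 lower named genes with the largest fold change among those past the threshold whose groups did not overlap, filled up to 5 by p value where fewer passed, and up to 4 members of each list with the smallest p. Genes outside that rule are named as well, among them neighbours on chromosomes and innervation genes.

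Alternatives comprised normexp background correction of the median intensities with quantile normalization (these files hold no mean intensity), quantile normalization alone, the deposited z-scores rescaled by the mean SD of 3.48, no filter or a filter on all arrays, outlier spots kept, the mean of a gene's probes, a mean-variance trend with robust variances, array weights, replicate number or slide as a block, only the groups compared, and each array left out. Leaving out both arrays of unusual signal spread was added after the array summaries were seen, and the SD of log2 signal as a covariate after its count for the averaged contrast was seen. On simulated data with 100 genes changed by 1 and 100 by 2 on the log2 scale, the model recovered 42%, 44% and 72% of the former for the genotype contrasts on SD, on HFHS and averaged, and 62%, 59% and 77% of the latter. It called 5, 5 and 11 unchanged genes, and no list that had not been shifted. The simulated genes varied independently and the simulated arrays shared 1 signal spread, unlike the real ones. These rates therefore need not hold for the real arrays, least of all for lists. The number of arrays limits the precision of every value. The treatment protocol also names an insulin receptor antagonist and vehicle, which no sample label assigns, so whether it applies to these arrays is not known.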

Results

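Gene expression was measured in skeletal muscle of 4 groups of male mice, WT and CB1KO, fed SD or HFHS, with 4 biological replicates per group and 1 array each. Between 56.7% and 75% of the non-control spots on an array stood well above background, and no spot was saturated. Pairs of arrays correlated across genes with Pearson r between 0.868 and 0.993. The arrays differed in the spread of their signal: the SD of log2 signal was 2.89 on CB1KO_SD replicate 2 and 3.97 on CB1KO_HFHS replicate 1, against 3.14 to 3.69 on the other arrays. The first principal component, with 51.6% of the variance, followed this spread (r = 0.973). All SD arrays shared 1 slide and all HFHS arrays the other, so diet and slide cannot be told apart. Within each slide, WT arrays filled 1 row and CB1KO arrays the other. Replicate number was the same as the slide column on every array, so the replicate block is a column block as well.

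The series title names muscle CB1 receptor, Il-6 and myostatin, so Cnr1, Il6 and Mstn were looked at first. Cnr1, which encodes the receptor, differed little between genotypes: the log2 fold change of CB1KO against WT was -0.23 ± 0.46 (SE) on SD (exact permutation p = 0.629) and -0.14 ± 0.46 on HFHS (exact p = 0.8). Whether its only probe lies in the part removed by Cre is not known, so this value does not test the knockout. Il6, the cytokine interleukin 6, averaged -0.93 ± 1.61 (SD, 4 arrays) in CB1KO_SD and -3.12 ± 0.50 in WT_SD, a log2 difference of 2.19 ± 0.62 (SE) that did not pass over all genes (adjusted p = 0.333, exact p = 0.0571). On HFHS the Il6 difference was 0.21 ± 0.62 (adjusted p = 0.923, exact p = 0.686), and the interaction did not pass either (-1.98 ± 0.88, adjusted p = 1). Mstn, which encodes myostatin, a secreted inhibitor of muscle growth, had log2 fold changes of -0.64 ± 0.44 on SD (adjusted p = 0.756, exact p = 0.257) and -0.88 ± 0.44 on HFHS (adjusted p = 0.598, exact p = 0.0857). With array weights the Mstn difference on HFHS passed, at -1.22 and adjusted p = 0.0342, and under the other alternatives its adjusted p lay between 0.239 and 0.715. The sign of the Cnr1 value turned without CB1KO_SD replicate 2 on SD (0.02) and without WT_HFHS replicate 4 (0.04), CB1KO_HFHS replicate 2 (0.04) or CB1KO_HFHS replicate 4 (0.02) on HFHS. That of Il6 on HFHS turned without CB1KO_HFHS replicate 4 (-0.14).

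**Figure D1:**
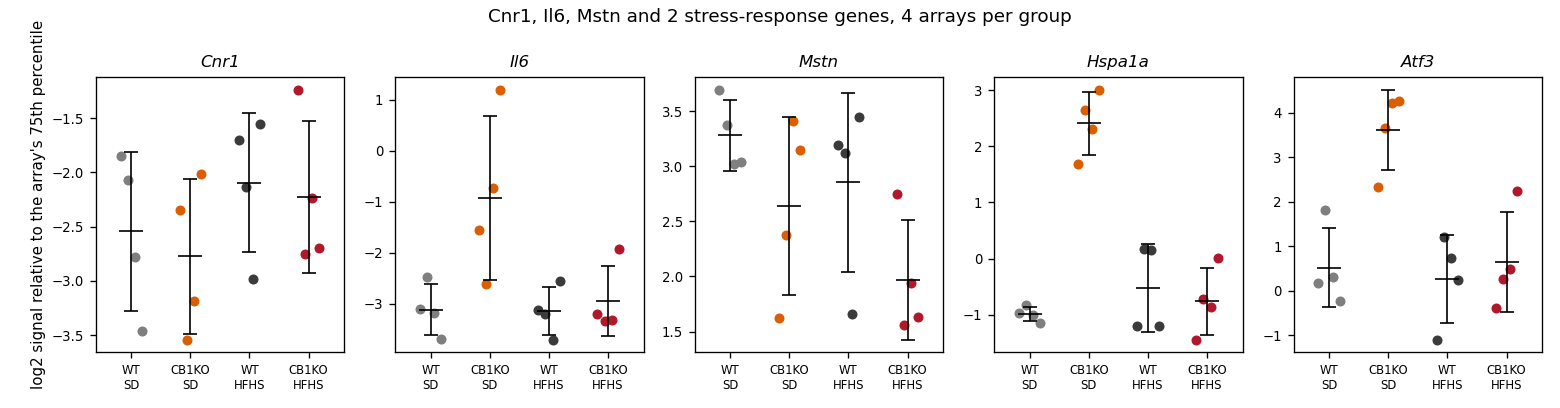
Log2 signal relative to the array's 75th percentile for Cnr1, Il6, Mstn and the stress-response genes Hspa1a and Atf3 on each array (points) with the group mean and SD (bars), 4 arrays per group. Hspa1a averaged 2.41 in CB1KO_SD and between -0.99 and -0.52 in the other groups, and Il6 was spread widely among the CB1KO_SD arrays.

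The comparison of CB1KO with WT averaged over both diets asks which genes differ with the receptor in muscle whatever the diet. Sln, encoding sarcolipin, a small inhibitor of the sarcoplasmic reticulum calcium pump, rose by 4.27 ± 0.50 (log2 fold change ± SE, adjusted p = 0.00218). Fgl1, a fibrinogen-like secreted protein, was at least 3.92-fold higher (adjusted p = 0.000945), with both WT groups near background. Plekhh1 rose by 2.66 ± 0.25 (adjusted p = 0.000945), Rgs2, a regulator of G protein signalling, by 1.55 ± 0.16 (adjusted p = 0.000945) and Chrna1, the alpha subunit of the muscle acetylcholine receptor, by 1.92 ± 0.31 (adjusted p = 0.0167). Among the genes that fell were Htra4, a serine protease, at -2.93 ± 0.43 (adjusted p = 0.0098), Snph, encoding the mitochondrial anchor syntaphilin, at -2.05 ± 0.26 (adjusted p = 0.00425), and Cd28, a T cell co-stimulatory receptor, at -1.85 ± 0.22 (adjusted p = 0.00235). Dnase1 fell as well, at -1.58 ± 0.25 (adjusted p = 0.0167), as did Kcnab1, a potassium channel subunit, at -1.35 ± 0.18 (adjusted p = 0.00559). Toporsl, Olfr486 and Nat1, near background in both CB1KO groups, were at least 1.06-fold, 1.09-fold and 1.77-fold lower. The call of Nat1 ended under both quantile alternatives. Each of these 13 genes passed in all 16 fits that left out 1 array.

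Further genes passed in the averaged comparison. Cdkn1a and Gadd45a, which act in growth arrest, and the metallothioneins Mt1 and Mt2 rose, by 1.54 ± 0.29 for Cdkn1a, 0.65 ± 0.12 for Gadd45a, 2.17 ± 0.40 for Mt2 and 1.62 ± 0.32 for Mt1 (adjusted p from 0.0261 to 0.0395). So did the interferon-induced Bst2 (1.64 ± 0.29), Cytip (1.46 ± 0.25) and Chrna9, another acetylcholine receptor subunit (2.33 ± 0.43). The average for Hspa1a (1.58 ± 0.27) passed as well but comes from SD alone, since on HFHS it averaged -0.76 in CB1KO and -0.52 in WT. Elf3 (-1.54 ± 0.26), Chac1, a glutathione-degrading enzyme (-0.82 ± 0.16), and Mylk2, the myosin light chain kinase of skeletal muscle (-0.64 ± 0.11), fell. Tmem252, with both WT groups near background, was at least 2.77-fold higher, and Serpind1, with both CB1KO groups near background, at least 1.41-fold lower. These 13 genes depended on single arrays, with no change of direction: 12, 1, 10 and 3 of them lost the threshold without WT_SD replicates 1, 2, 3 and 4, and 2, 1 and 7 without CB1KO_SD replicates 1, 3 and 4. Without WT_HFHS replicates 1, 2, 3 and 4 it was 7, 11, 2 and 10 of them, and without CB1KO_HFHS replicates 2, 3 and 4 it was 3, 7 and 7, with adjusted p up to 0.0951. Serpind1 lost it only without WT_HFHS replicate 2 (adjusted p = 0.0519). The replicate block ended the calls of Chrna9, Tmem252, Bst2, Mt1, Cdkn1a, Mylk2, Mt2 and Chac1, and the slide block those of Gadd45a and Hspa1a. The mean of a gene's probes ended those of Cdkn1a and Mt1, and no filter that of Mt1. The rise of Cdkn1a rests on 1 of its 2 probes, the other giving -0.07. At least 1 of the normalizations ended those of Elf3, Serpind1, Tmem252, Cytip, Mylk2 and Chac1.

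In all, 205 genes passed in the averaged comparison, 92 higher and 113 lower in CB1KO, and 127 of them have a symbol. The share of lower genes depended on the fit: 356 higher and 1396 lower passed with the SD of log2 signal as a covariate, 669 and 1224 with array weights, 299 and 592 without both arrays of unusual signal spread, and 36 and 23 with the replicate block. Across all genes, which are not independent replicates, the genotype effects on SD and on HFHS correlated with Pearson r = 0.391 and Spearman rho = 0.329. The median of all genes lay at -0.12 under the 75th percentile scaling and at -0.04 under quantile normalization, and list shifts below are relative to it. The count changed by more than 1.5 times when single arrays were left out: to 56, 61, 115, 617, 317 and 98 genes without WT_SD replicate 1, WT_SD replicate 3 and CB1KO_SD replicates 1, 2, 3 and 4, and to 90, 47, 59, 311, 102, 71 and 82 without WT_HFHS replicates 1, 2 and 4 and CB1KO_HFHS replicates 1, 2, 3 and 4. Without both arrays of unusual signal spread, an alternative chosen after seeing the data, it was 891, 204 of them shared with the 205.

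**Figure D2:**
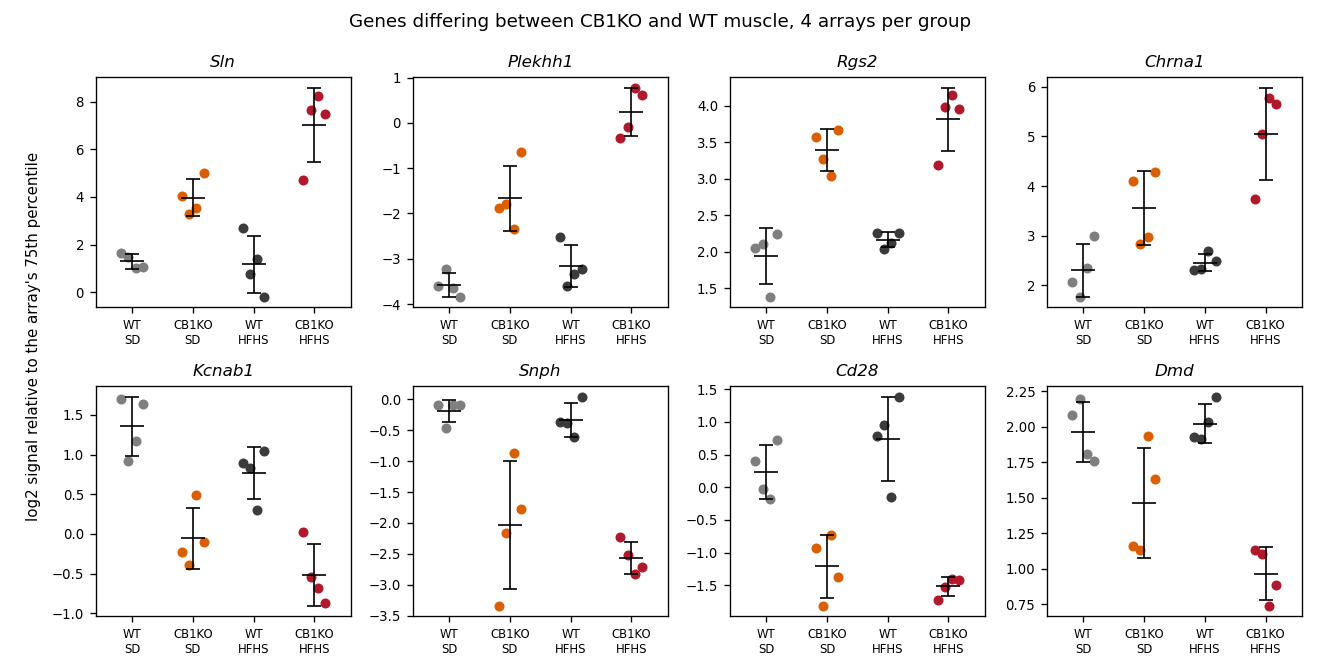
Log2 signal relative to the array's 75th percentile for 8 genes on each array (points) with the group mean and SD (bars), 4 arrays per group. Sln averaged 3.97 in CB1KO_SD and 7.02 in CB1KO_HFHS against 1.29 and 1.16 in the WT groups, and Kcnab1, Snph and Cd28 were lower in CB1KO on both diets.

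Several gene lists lay higher in CB1KO averaged over diets. The list of myogenesis and regeneration genes had 19 of 23 members above the median gene and a median shift of 0.26 (camera adjusted p = 2.31e-08, but adjusted p = 0.0831 with an estimated correlation). Chrna1 passed, and Myod1 and Myog, transcription factors of muscle differentiation, had 0.97 ± 0.22 and 1.17 ± 0.33. Inflammatory cytokines and chemokines had 19 of 21 members above it and a median shift of 0.52 (adjusted p = 3.86e-08, and adjusted p = 0.099 with an estimated correlation), among them Ccl7 (1.56 ± 0.42) and Cxcl10 (1.13 ± 0.39), neither of which passed. All 16 macrophage markers lay above the median gene, with a median shift of 0.68 (adjusted p = 2.31e-08), as did 16 of 17 slow-twitch fibre genes (0.94, adjusted p = 9.41e-07), and both had adjusted p = 0.45 with an estimated correlation. The same held for 25 of 31 MAP kinase and immediate early genes (0.30, adjusted p = 4.26e-07), 23 of 24 collagen and matrix genes (0.32, adjusted p = 9.41e-07) and 22 of 24 interferon response genes (0.34, adjusted p = 1.5e-06). For these 3 lists, and for the neutrophil markers (0.19, adjusted p = 0.0337), that value was 0.45 too. Fibroblast markers shifted by 0.22 (adjusted p = 0.0397, and adjusted p = 0.775 with an estimated correlation). The slow-twitch, MAP kinase and neutrophil averages rest mainly on SD, and none of these lists was called on HFHS. Their means over members differed between CB1KO and WT by 2.04, 0.80 and 0.45 on SD. On HFHS the differences were -0.19, 0.10 and -0.01. The fibroblast list went the other way, with -0.01 on SD and 0.19 on HFHS. Oxidative phosphorylation was called lower by camera (adjusted p = 0.00783, and adjusted p = 0.934 with an estimated correlation), although its median shift was -0.01 and its mean shift 0.02, so the signs differ, and the median was 0.02 under quantile normalization. This call ended under all 3 normalizations, with array weights (adjusted p = 0.921) and without both arrays of unusual spread (0.953). The neutrophil and fibroblast calls ended on the z-scores, with array weights and without both arrays, and the fibroblast call also with either change of filter and with the SD covariate. Single arrays moved several shifts by over 1.5 times: slow-twitch genes to 0.40 without WT_SD replicate 1, to 0.38 without WT_HFHS replicate 4 and to 0.45 without CB1KO_HFHS replicate 2, interferon response genes to 0.16 without CB1KO_HFHS replicate 2, and collagen to 0.21 without CB1KO_HFHS replicate 1. Neutrophil markers moved to 0.08 without CB1KO_SD replicate 2, and fibroblast markers to 0.14 and 0.07 without CB1KO_SD replicate 1 and CB1KO_HFHS replicate 1. The median shift of oxidative phosphorylation stayed between -0.04 and 0.04 without any 1 array. The oxidative phosphorylation call ended without WT_SD replicate 2, CB1KO_SD replicate 2, WT_HFHS replicate 3 or CB1KO_HFHS replicate 1 (adjusted p up to 0.623), and the neutrophil call without CB1KO_SD replicate 2 or CB1KO_HFHS replicate 4 (up to 0.233). The fibroblast call ended without WT_SD replicates 1, 3 or 4, CB1KO_SD replicates 1 or 4, WT_HFHS replicates 2 or 3 or CB1KO_HFHS replicate 1 (up to 0.468). Among the genes of muscle atrophy, proteolysis and autophagy, 4 passed over all genes (Mt2, Gadd45a, Cdkn1a and Mt1), and 4 higher and 1 lower passed when adjusted over the list alone. That list was not called as a whole (median shift 0.07, adjusted p = 0.197), while fry's mixed test, which asks for change in either direction, gave adjusted p = 1.34e-05. By the preset test 10 of the 37 lists passed, and 0 passed with an estimated correlation or with fry, whose mixed test called 6. Without CB1KO_SD replicate 2 the preset count was 17.

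On SD alone, CB1KO against WT asks for the genotype effect under ordinary feeding. Hspa1a, which encodes the inducible heat shock protein 70, rose by 3.4 ± 0.38 on the log2 scale (adjusted p = 0.0125) and was the only gene to pass. Dnajb1, its co-chaperone, had 2.26 ± 0.45 (adjusted p = 0.148), Atf3, a stress-induced transcription factor, had 3.10 ± 0.65 (adjusted p = 0.184), and Egr2 had 1.82 ± 0.46 (adjusted p = 0.271). Other genes with small p values did not pass: Rgs2 (1.44 ± 0.23), Otud1 (2.84 ± 0.50) and Has1, a hyaluronan synthase (3.80 ± 0.68), on the higher side, and Kcnab1 (-1.41 ± 0.26) and Rnf126 (-0.69 ± 0.13) on the lower, with adjusted p from 0.0596 to 0.141. Zfp709 lay higher in CB1KO, with WT_SD near background, and Serpind1 (at least 1.71-fold), Olfr486 (at least 1.19-fold) and Toporsl lay lower with CB1KO_SD near background, and none of these passed (adjusted p from 0.0596 to 0.138). Hspa1a lost the threshold without WT_SD replicate 1 (adjusted p = 0.0771), WT_SD replicate 3 (0.0802) or CB1KO_SD replicate 4 (0.0778) and in the fit of these 2 groups alone. The gene count was 0, 7, 0 and 3 without WT_SD replicates 1, 2, 3 and 4 and 7, 26, 5 and 0 without CB1KO_SD replicates 1, 2, 3 and 4. At an unadjusted p under 0.05 there were 2527 genes, and the alternatives gave between 0 and 236 genes past the threshold.

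Among the gene lists on SD, all 17 slow-twitch genes lay above the median gene, with a median shift of 2.39 (camera adjusted p = 4.07e-12, but adjusted p = 0.279 with an estimated correlation), for example Tnni1, slow troponin I (2.45 ± 0.99), and Atp2a2, the slow calcium pump (1.70 ± 0.70). Fast-twitch genes lay lower (-0.10, adjusted p = 0.00456, and adjusted p = 0.698 with an estimated correlation), among them Mylk2 (-0.69 ± 0.16) and Actn3 (-0.45 ± 0.14), and this call ended under both quantile alternatives and on the z-scores, and without WT_SD replicate 2 (adjusted p = 0.0686). MAP kinase and immediate early genes shifted by 0.38 (adjusted p = 1.1e-09, but adjusted p = 0.191 with an estimated correlation), with 25 of 31 above the median gene and 6 higher when adjusted over the list alone. Inflammatory cytokines shifted by 0.47 (adjusted p = 1.66e-06), with Ccl2 at 1.48 ± 0.52, and myogenesis genes by 0.32 (adjusted p = 3.48e-06). Both had the same adjusted p = 0.191 with an estimated correlation. Fatty acid uptake and oxidation genes shifted by 0.38 (adjusted p = 5.1e-08, and adjusted p = 0.684 with an estimated correlation). Without WT_SD replicate 1 the shift of slow-twitch genes was 1.54, of fatty acid oxidation 0.25 and of cytokines 0.25, and without CB1KO_SD replicate 4 that of cytokines was 0.29. The fast-twitch shift was -0.05, -0.16, -0.26 and -0.05 without WT_SD replicates 2 and 3 and CB1KO_SD replicates 2 and 3. The remaining called lists were the interferon response (0.26), neutrophil (0.23), macrophage (0.26), endothelial (0.23) and smooth muscle markers (0.31), collagen (0.16), mitochondrial biogenesis (0.17), the tricarboxylic acid cycle (0.14), oxidative phosphorylation (0.12) and interleukin 6 signalling (0.03). Their adjusted p values ran from 0.00346 to 0.0453, and the least was adjusted p = 0.489 with an estimated correlation. Oxidative phosphorylation lay higher only relative to the median gene, which was at -0.12. Its mean over members differed between CB1KO and WT by 0.0055 (exact permutation p = 0.971). Of these 10 lists, 9, 3 and 6 lost the threshold without WT_SD replicates 1, 3 and 4 and 4, 1, 5 and 8 without CB1KO_SD replicates 1, 2, 3 and 4 (adjusted p up to 0.93). The shifts of these 10 moved by over 1.5 times without 1 or more of the 8 arrays. Extremes were macrophages at 0.10 and 0.64 without WT_SD replicates 1 and 4, collagen at 0.00 and 0.31 without CB1KO_SD replicates 1 and 3, smooth muscle at 0.07 without CB1KO_SD replicate 1, mitochondrial biogenesis at 0.02 without WT_SD replicate 4, and oxidative phosphorylation at 0.23 and neutrophils at 0.09 without CB1KO_SD replicate 2. Other alternatives ended calls among them too: all 3 normalizations those of macrophages and interleukin 6 signalling, both quantile alternatives that of interferon, normexp that of collagen, and the z-scores and the SD covariate that of smooth muscle. Array weights and leaving out both arrays of unusual spread ended the neutrophil call, and no filter that of oxidative phosphorylation. The call of interleukin 6 signalling also ended with either change of filter, in the fit of 2 groups and with the SD covariate. Its shift turned to -0.04 without WT_SD replicate 1 and to -0.01 under normexp. Camera called 16 lists at the preset correlation, 7 without WT_SD replicate 1 and 8 without CB1KO_SD replicate 4, and 0 with an estimated correlation or fry. Fry's mixed test called 2, the immediate early genes and the heat shock and endoplasmic reticulum stress genes.

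On HFHS, the same comparison asks for the genotype effect in diet-fed animals. Gsdma, encoding gasdermin A, rose by 3.59 ± 0.36 (adjusted p = 0.0021) and Plekhh1 by 3.41 ± 0.35 (adjusted p = 0.0021). With WT_HFHS near background, Fgl1 was at least 11.1-fold higher, Sgk2, a kinase related to the serum and glucocorticoid regulated kinase, at least 6.65-fold, Dnajc5g at least 6.14-fold, Maats1 at least 4.47-fold and Arhgap36 at least 3.52-fold (adjusted p from 0.00276 to 0.00833). These 7 passed without any 1 of the 8 arrays. Sln rose by 5.86 ± 0.71 (adjusted p = 0.00399), and its call ended when these 2 groups were fitted alone. Degs2 (-1.44 ± 0.16), Cd28 (-2.25 ± 0.31) and Toporsl (at least 1.21-fold lower, CB1KO_HFHS near background) fell, and each of these calls ended under at least 1 of the quantile alternatives, that of Degs2 also on the z-scores and that of Cd28 also in the fit of 2 groups. Chrna1 (2.59 ± 0.44), Gadd45a (1.1 ± 0.17), Psat1, an enzyme of serine synthesis (2.12 ± 0.37), Shisal1 (3.37 ± 0.55) and Acsm4 (at least 2.29-fold, WT_HFHS near background) rose too. Snph (-2.24 ± 0.37), Dnase1 (-2.11 ± 0.36), Nat1 (at least 2.35-fold lower, CB1KO_HFHS near background), Stab2, a scavenger receptor (-1.35 ± 0.24), Foxd3 (-1.20 ± 0.18), Dmd, encoding dystrophin (-1.06 ± 0.18), and Tmem47 (-0.99 ± 0.18) fell. These had adjusted p from 0.0135 to 0.0393. Of these 12 genes, 11, 12, 10 and 9 lost the threshold without WT_HFHS replicates 1, 2, 3 and 4 and 7, 11 and 11 without CB1KO_HFHS replicates 2, 3 and 4, with adjusted p up to 0.168. Among single arrays, only WT_HFHS replicate 2 ended the call of Foxd3 (adjusted p = 0.0634). Its call also ended under both quantile alternatives, on the z-scores, with the replicate block and in the fit of 2 groups, as did those of Nat1 and Tmem47. Tmem47 lost it without a filter and with the trend too. The replicate block also ended the calls of Snph, Stab2, Dmd and Psat1, the z-scores those of Snph, Dnase1, Dmd and Psat1, quantile normalization those of Snph and Psat1, and the fit of 2 groups those of Dnase1, Stab2, Chrna1 and Psat1. Psat1 also lost it with the mean of its probes, since its other probe gave 0.37.

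In all, 68 genes passed on HFHS, 49 higher and 19 lower. The excess of higher genes depended on the fit: 142 higher and 213 lower passed with the SD of log2 signal as a covariate, 813 and 1193 with array weights, and 107 and 86 without both arrays of unusual signal spread. Of the 68, 62 lay in the same direction on SD, and 39 did so with an unadjusted p under 0.05 there, against 2.97 expected for genes drawn at random. Both contrasts share each gene's residual spread, so genes picked on HFHS tend to have smaller p on SD too. The 2.97 is thus too low a reference. The count was 27, 21, 28 and 32 without WT_HFHS replicates 1, 2, 3 and 4 and 133, 43, 20 and 25 without CB1KO_HFHS replicates 1, 2, 3 and 4. It was 193, 67 of them shared with the 68, without both arrays of unusual signal spread.

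Among the gene lists on HFHS, all 16 macrophage markers lay above the median gene, with a median shift of 1.14 (camera adjusted p = 1.61e-10, and adjusted p = 0.369 with an estimated correlation), for example Itgax (1.65 ± 0.55) and Cd68 (1.29 ± 0.50), and so did 23 of 24 collagen and matrix genes (0.52, adjusted p = 6.95e-07, and adjusted p = 0.687 with an estimated correlation). Myogenesis genes shifted by 0.46 (adjusted p = 6.95e-07, and adjusted p = 0.206 with an estimated correlation), with 20 of 23 above the median gene, 1 past the threshold over all genes (Chrna1) and 3 when adjusted over the list alone. Interferon response genes shifted by 0.39 (adjusted p = 5.25e-06, and adjusted p = 0.738 with an estimated correlation), cytokines by 0.55 (adjusted p = 7.75e-05, and adjusted p = 0.369 with an estimated correlation) and lymphocyte markers by 0.50 (adjusted p = 0.00551, and adjusted p = 0.687 with an estimated correlation). Oxidative phosphorylation lay lower, with 6 of 78 genes above the median gene and a median shift of -0.12 (adjusted p = 6.19e-11), and so did fatty acid oxidation (-0.19, adjusted p = 0.0124) and smooth muscle markers (-0.23, adjusted p = 0.0266), while fibroblast markers shifted by 0.29 (adjusted p = 0.0124). Each of these 4 had adjusted p = 0.779 with an estimated correlation. The interferon call ended without CB1KO_HFHS replicate 2 (adjusted p = 0.115), the lymphocyte call without CB1KO_HFHS replicate 3 (adjusted p = 0.137), and the fatty acid, fibroblast and smooth muscle calls without WT_HFHS replicates 2 or 3. The fatty acid and fibroblast calls also ended without CB1KO_HFHS replicate 1, and the fatty acid and smooth muscle calls without CB1KO_HFHS replicate 3 (adjusted p up to 0.534). Single arrays moved other shifts by over 1.5 times: collagen to 0.22 and cytokines to 0.36 without CB1KO_HFHS replicate 1, myogenesis to 0.30 and 0.27 without WT_HFHS replicates 2 and 3, and lymphocytes to 0.25 without WT_HFHS replicate 1. Oxidative phosphorylation moved to -0.08 without WT_HFHS replicate 3, and fatty acid oxidation to -0.08, -0.30 and -0.29 without WT_HFHS replicates 3 and 4 and CB1KO_HFHS replicate 2. Where a call ended, the shift was 0.07 for interferon, 0.14 for lymphocytes and 0.07 for fibroblasts (without CB1KO_HFHS replicate 1). Dropping both arrays of unusual spread or adding the SD covariate ended the fatty acid and fibroblast calls, array weights the fibroblast call, the fit of 2 groups the fatty acid call, and the filter on all arrays the lymphocyte call. The preset test called 10 lists, and 0 passed with an estimated correlation or fry, whose mixed test called 3 (myogenesis, atrophy, and mitochondrial and one-carbon stress).

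**Figure D3:**
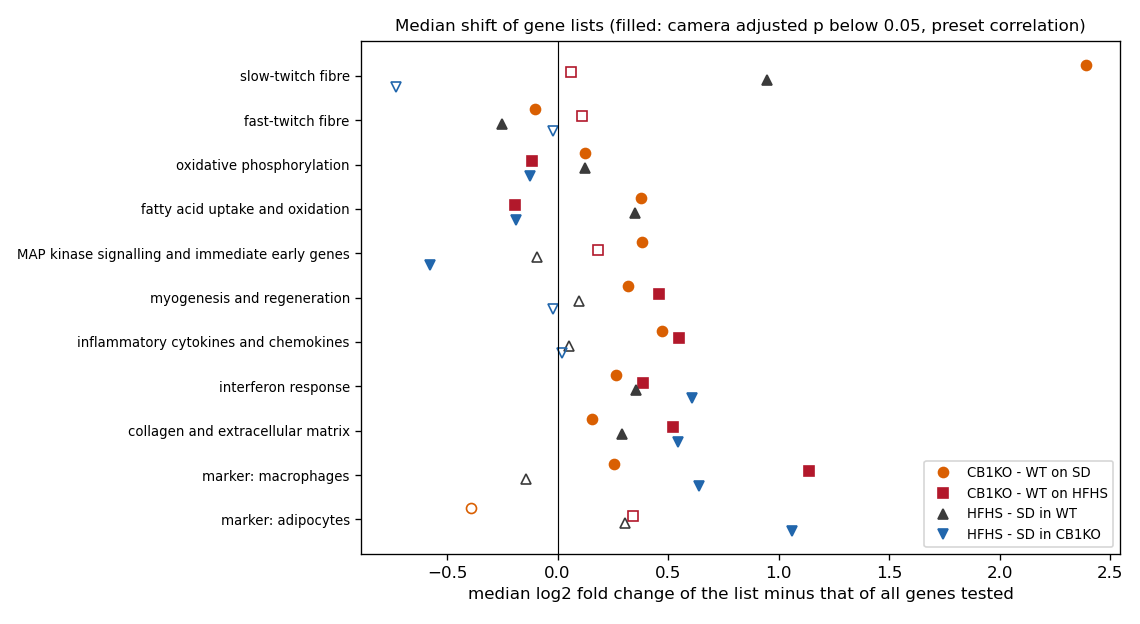
Median log2 fold change of 11 gene lists minus that of all genes tested, by contrast (symbols), filled where camera's adjusted p at the preset correlation was below the threshold. Slow-twitch genes shifted by 2.39 between CB1KO and WT on SD, and none of the shifts passed with an estimated correlation. Oxidative phosphorylation for HFHS against SD in WT turns to -0.19 on the z-scores.

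The genotype-by-diet interaction asks whether the knockout acts differently on the 2 diets. Hspa1a came closest, with -3.64 ± 0.54 (adjusted p = 0.305), followed by Nkx6-2, Slc38a11 and Gsdma (adjusted p = 0.854 each), and no gene passed in limma, with 1024 at an unadjusted p under 0.05. Normexp with quantile normalization gave 1 gene, and leaving out CB1KO_HFHS replicate 1 gave 11 genes. At the level of lists, the genotype effect on HFHS lay below that on SD for slow-twitch genes (median shift -1.62, camera adjusted p = 4.39e-05, but adjusted p = 0.612 with an estimated correlation), fatty acid oxidation (-0.55, adjusted p = 6.86e-12), oxidative phosphorylation (-0.27, adjusted p = 5.96e-16), the tricarboxylic acid cycle (-0.22), mitochondrial biogenesis (-0.21), immediate early genes (-0.51) and smooth muscle (-0.47) and endothelial markers (-0.32), each with that same 0.612. It lay above that on SD for macrophage (0.86) and lymphocyte markers (0.45) and, by the median shift, fast-twitch genes (0.18). The mean over fast-twitch members did not go this way: CB1KO minus WT was -0.16 on SD and -0.19 on HFHS. The 11 lists had adjusted p up to 0.00692, and each had 0.612 with an estimated correlation, where 0 were called, as with fry. Single arrays moved shifts by over 1.5 times: slow-twitch to -1.03 without WT_HFHS replicate 3, immediate early genes to -0.32, -0.31 and -0.30 without CB1KO_SD replicate 4, WT_HFHS replicate 4 and CB1KO_HFHS replicate 2, and endothelium to -0.20 without CB1KO_SD replicate 1. The tricarboxylic acid cycle moved to -0.12 and -0.40 without WT_SD replicate 1 and CB1KO_SD replicate 2, and mitochondrial biogenesis to -0.33, -0.14, -0.40 and -0.11 without WT_SD replicates 2 and 4 and CB1KO_SD replicates 2 and 3. Fast-twitch genes moved to 0.10, 0.31, 0.12 and 0.28 without WT_SD replicate 2, CB1KO_SD replicate 2, WT_HFHS replicate 1 and CB1KO_HFHS replicate 3, and macrophages to 0.41 and 0.45 without WT_SD replicate 4 and CB1KO_HFHS replicate 1. All 3 normalizations ended the fast-twitch call, quantile normalization the lymphocyte call, and array weights or leaving out both arrays of unusual spread the macrophage call. The macrophage call ended without WT_SD replicate 4 or CB1KO_HFHS replicate 1, the lymphocyte call without CB1KO_HFHS replicate 3 and the fast-twitch call without WT_SD replicate 2 or CB1KO_HFHS replicate 2, with adjusted p up to 0.0835, 0.107 and 0.0799.

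HFHS against SD in WT asks what the diet does to normal muscle, with slide and diet inseparable. Ubd, a ubiquitin-like modifier induced in inflammation, had 3.57 ± 0.75 (adjusted p = 0.43), Tnfaip2 had 1.00 ± 0.20 (adjusted p = 0.43) and Pde8b, a phosphodiesterase, 0.82 ± 0.17 (adjusted p = 0.445), while Tmem100 had -1.62 ± 0.29 (adjusted p = 0.37). Zfp709 came closest to passing (at least 1.23-fold higher with WT_SD near background, adjusted p = 0.0963). No gene passed in limma, with 1745 at an unadjusted p under 0.05, and 99 passed with array weights. Camera called 12 lists at the preset correlation, and 0 were called with an estimated correlation or fry. Slow-twitch genes shifted by 0.95 (adjusted p = 0.00271, and adjusted p = 0.805 with an estimated correlation), fatty acid oxidation by 0.35 (adjusted p = 8.78e-07, and again 0.805), interferon response genes by 0.35, smooth muscle markers by 0.45, and endothelial markers by 0.32. The other lists called were fibroblast markers, shifted by 0.33, collagen by 0.29, mitochondrial biogenesis by 0.24, the tricarboxylic acid cycle by 0.17, oxidative phosphorylation by 0.12, insulin signalling by 0.16 and fast-twitch genes by -0.25. For these 12 lists the preset adjusted p was at most 0.0494, and at least 0.794 with an estimated correlation. On the z-scores the shifts of oxidative phosphorylation and the tricarboxylic acid cycle turned to -0.19 and -0.13, where the first still passed (adjusted p = 0.000168) and the second did not (0.534). Single arrays moved shifts by over 1.5 times: slow-twitch to 0.23, 0.36 and 1.67 without WT_SD replicate 1 and WT_HFHS replicates 3 and 4, and fatty acid oxidation to 0.21 and 0.22 without WT_SD replicate 1 and WT_HFHS replicate 3. Without WT_SD replicates 1, 2 and 4, oxidative phosphorylation moved to 0.06, 0.24 and 0.08 and the tricarboxylic acid cycle to 0.06, 0.28 and 0.10. Fast-twitch genes moved to -0.16 without WT_SD replicate 2, mitochondrial biogenesis to 0.11 without WT_SD replicate 4, and interferon and fibroblast genes to 0.23 and 0.13 without WT_HFHS replicate 1. Insulin signalling moved to 0.07, 0.09 and 0.10 without WT_SD replicates 1 and 4 and WT_HFHS replicate 4. Both quantile alternatives ended the fast-twitch and insulin calls, and the insulin call also ended on the z-scores, with the filter on all arrays, the mean of a gene's probes, the replicate block and the fit of 2 groups. The SD of log2 signal as a covariate ended 6 of the 12, those of oxidative phosphorylation, the tricarboxylic acid cycle, mitochondrial biogenesis, insulin signalling, collagen and fibroblasts. Leaving out WT_SD replicate 1 or WT_HFHS replicate 3 ended the slow-twitch and tricarboxylic acid calls, and the latter array that of oxidative phosphorylation (adjusted p up to 0.379). The collagen and fibroblast calls ended without WT_HFHS replicate 1 (up to 0.0784), and the insulin call without WT_SD replicates 1 or 4 or WT_HFHS replicates 1, 2 or 4 (up to 0.413).

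HFHS against SD in CB1KO asks for the diet effect without the receptor in muscle, again across slides. Hspa1a fell, at -3.17 ± 0.38 (adjusted p = 0.0173), as did Dbndd1 at -1.39 ± 0.18 (adjusted p = 0.0173), and Rab13, a small GTPase, rose by 0.88 ± 0.13 (adjusted p = 0.032). Ubd (4.56 ± 0.75), Psat1 (2.28 ± 0.37), Tmem229b (1.14 ± 0.19) and Cited1 (1.30 ± 0.22) on the higher side and Kcnn2, a calcium-activated potassium channel (-1.51 ± 0.26), Nfkbiz (-1.24 ± 0.22) and Degs2 (-0.90 ± 0.16) on the lower had adjusted p from 0.0778 to 0.0852, and the other probe of Psat1 gave 0.30. In all 8 genes passed, 4 in each direction, of which 3 have a symbol, and 2770 had an unadjusted p under 0.05. The count was 24, 0, 30, 0, 0 and 3 without CB1KO_SD replicates 1 and 3 and CB1KO_HFHS replicates 1, 2, 3 and 4, and all 3 named calls ended without CB1KO_SD replicate 3 or CB1KO_HFHS replicates 2 or 3, and those of Rab13 and Dbndd1 without CB1KO_HFHS replicate 4 (adjusted p up to 0.177). The replicate block and the fit of 2 groups ended all 3. Both quantile alternatives, the z-scores and the trend ended those of Rab13 and Dbndd1, and no filter that of Rab13, so of the 3 only Hspa1a passed under every normalization. Immediate early genes lay lower (median shift -0.58, camera adjusted p = 6.03e-05, but adjusted p = 0.714 with an estimated correlation), with Jun at -1.12 ± 0.23 and Atf3 at -2.97 ± 0.65 and 11 of 31 lower when adjusted over the list alone. Interferon response genes (0.61, adjusted p = 3.48e-07), collagen (0.55, adjusted p = 2.43e-06), fibroblast (0.53, adjusted p = 2.37e-05) and lymphocyte markers (0.64, adjusted p = 0.000524) lay higher. These 4 lists also had adjusted p = 0.714 with an estimated correlation. Adipocyte markers (1.06, adjusted p = 0.001), macrophage markers (0.64, adjusted p = 0.00129), oxidative phosphorylation (-0.12, adjusted p = 3.48e-07) and fatty acid oxidation (-0.19, adjusted p = 0.00482) each had adjusted p = 0.918 with an estimated correlation, and 0 of the 37 lists passed with that estimate or with fry, whose mixed test called 7. Without both arrays of unusual spread the collagen, fibroblast, macrophage and adipocyte calls ended, and other alternatives ended those of macrophages (array weights), adipocytes (z-scores and the SD covariate), fatty acid oxidation (no filter) and lymphocytes (the filter on all arrays). Without CB1KO_HFHS replicate 1 the shift of collagen was 0.30, of fibroblasts 0.35, of macrophages 0.29 and of adipocytes 0.65, and without CB1KO_HFHS replicate 2 that of interferon genes was 0.33. Oxidative phosphorylation moved to -0.25 and -0.07 without CB1KO_SD replicates 2 and 4, and fatty acid oxidation to -0.11, -0.34 and -0.29 without CB1KO_SD replicates 1 and 2 and CB1KO_HFHS replicate 2. The adipocyte call ended without CB1KO_HFHS replicate 1 (adjusted p = 0.0793), the macrophage call without that array or CB1KO_SD replicate 3 (up to 0.129) and the fatty acid call without that array or CB1KO_SD replicate 1 (up to 0.26). The preset count of 9 lists was 15 without CB1KO_SD replicate 2.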

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

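The tests of slide position, of the stress genes on z-scores and of neighbouring genes were chosen after the results they concern were seen.

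The 205 genes past the threshold between CB1KO and WT averaged over diets, Sln, Plekhh1, Rgs2, Snph and Cd28 among them, were set against differences in signal spread and fibre content. With the SD of log2 signal as a covariate, their fold changes were a median of 1.0051 times those without (quartiles 0.983 to 1.03), and all 205 still passed. This SD averaged 3.47 over WT and 3.52 over CB1KO arrays. A covariate so nearly balanced between genotypes could hardly move the fold changes, so the ratio says little about the spread. With the slow-twitch score as a covariate the ratio was 0.9802 (quartiles 0.940 to 1.01) and the median SE went from 0.191 to 0.186. The slope on the score is fitted within groups, where genes past the threshold tend to vary little. A ratio near 1 was thus likely in advance and does not decide on the share of slow fibres. Only 104 of the 205 passed, and why the other calls ended was not tested. Slide row and genotype part on 0 arrays, so the position on the slide and the genotype cannot be told apart, and loss of the receptor stays a hypothesis.

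The 53 immediate early and heat shock genes, such as Atf3, Egr2, Hspa1a and Dnajb1, averaged 0.553 higher in CB1KO_SD than in WT_SD. The parts differ: the immediate early list was 0.801 higher (exact p = 0.0286, the smallest possible), and the heat shock and endoplasmic reticulum stress list 0.203 (exact p = 0.257). Without the CB1KO_SD array of the highest score, 0.8443 of the difference was left, which argues against a single array. On z-scores, where every array has the same spread, 1.1452 of it was left. The SD of log2 signal ran from 3.14 to 3.69 in WT_SD and from 2.89 to 3.62 in CB1KO_SD. With ranges that overlap so, making the spread equal could hardly remove the difference, and this test says little about the spread. Within groups Il6 went with the score (Pearson r = 0.7358, permutation p = 0.00047, and Spearman rho = 0.8). The permutation shuffled deviations from the group means over all arrays rather than within groups. Il6 varied more in CB1KO_SD (SD 1.61) than in the other groups (0.47 to 0.69), so this p may be too small. Immediate early and heat shock genes respond within minutes to hypoxia and handling, so tissue collection may explain the difference. A genotype effect that varied in size between animals would give such a correlation as well, so these cannot be told apart.

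Some called genes lie beside each other on chromosomes. Of the 127 called named genes, 18 have another called gene within 5 tested genes, against a median of 10 in random sets of as many genes (permutation p = 0.0346). Examples, named for their position after their values were seen, are Fgf20 with Cnot7 and Vps37a, Tbx2 with Tbx4 and Ints2, and Mt1 with Mt2, a pair of paralogues. Strain variants in segments that differ between the genotypes could give such clusters, and so could shared regulation. A window of up to 500 tested genes on either side of Cnr1 held 579 genes. Of these, 7 were called (named for the same reason: Glipr2, Toporsl, Ptgr1, Cdkn2a, Foxd3, Skint2 and Ccdc163) against 4.51 expected (one-sided Fisher's exact test, p = 0.166), too few to decide on linked variants. The window is wide, so these genes need not lie close to Cnr1.

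The arrays were split into other groups of the same sizes, to see how often a split gives as many calls as the real one. For genes, only the real split gave as many for CB1KO against WT on HFHS (1 of 35 splits, real 68, highest other 0). The same held averaged over diets (1 of 100, real 205, highest other 18) and for HFHS against SD in CB1KO (1 of 35, real 8, highest other 2). Chance is not excluded by this: the splits are few, and no correction was made for the several comparisons. A split that mixes groups with a real difference also has a wider residual spread, which lowers its count. For CB1KO against WT on SD, 4 of 35 splits gave as many (real 1, highest other 5089). With a real count of 0, every split gives as many, so the splits say nothing for the interaction (100 of 100, highest other 4795) and for HFHS against SD in WT (35 of 35, highest other 0). The 2 highest counts point to a structure among the arrays: the split with 5089 genes sets WT_SD replicates 1, 3 and 4 and CB1KO_SD replicate 2 against the rest. These arrays have the lowest SD of log2 signal on the SD slide (2.89 to 3.44, against 3.56 to 3.69), so this split follows the signal spread. For gene lists at the preset correlation, other splits gave as many in every comparison, so chance stays open there too. On SD, 10 of 35 splits gave as many (real 16, highest other 25), on HFHS 29 of 35 (10 and 19), averaged over diets 72 of 100 (10 and 26), for the interaction 58 of 100 (11 and 26), and for the diet in WT 23 of 35 (12 and 23) and in CB1KO 24 of 35 (9 and 19).

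Single arrays lay far from the others of their group in 27 of 520 tests, where chance gives about 26. The values here are the gap to the nearest array over the group's range. WT_HFHS replicate 4 had the lowest share of spots well above background (62.4% against 74.1%, gap 0.929), and CB1KO_SD replicate 2 the lowest SD of log2 signal (2.89 against 3.56, gap 0.924). In WT_SD, replicate 4 was highest for C1qb (0.867), Cd14 (0.936) and Myog (0.836), replicate 2 highest for Dnase1 (0.855) and lowest for Snph (0.986), and replicate 3 highest for Jchain (0.843) and the brown adipocyte score (0.927). In CB1KO_SD, replicate 2 was lowest for Acaa2 (0.941) and Ppargc1a (0.838) and highest for the fast-twitch score (0.88), replicate 3 lowest for Lep (0.892) and Maats1 (0.93), and replicate 1 highest for Nkx6-2 (0.845). In WT_HFHS, replicate 1 was highest for C1qb (0.901) and Psat1 (0.881) and lowest for Toporsl (0.949), replicate 3 highest for Col4a2 (0.838) and replicate 4 for Egr2 (0.882). In CB1KO_HFHS, replicate 4 was highest for Il6 (0.894) and Jun (0.919), replicate 1 lowest for Serpind1 (0.945) and highest for the fatty acid synthesis (0.869) and macrophage scores (0.845), replicate 2 highest for Tmem252 (0.899) and replicate 3 for the lymphocyte score (0.916).

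The genotype effect differed between diets for 11 lists by camera at the preset correlation. Median shifts of the interaction were -0.2735 for oxidative phosphorylation, -0.554 for fatty acid oxidation, -1.6166 for slow-twitch genes, -0.4746 for smooth muscle, -0.2197 for the tricarboxylic acid cycle and -0.2067 for mitochondrial biogenesis. They were 0.856 for macrophages, -0.324 for endothelium, -0.5073 for immediate early genes, 0.1785 for fast-twitch genes and 0.4504 for lymphocytes. Each had adjusted p = 0.612 with an estimated correlation. For fast-twitch genes the mean over members did not go with the median shift: CB1KO minus WT was -0.16 on SD and -0.19 on HFHS.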

How the results depend on the processing

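Leaving out both arrays of unusual spread and using the SD of log2 signal as a covariate were chosen after the data were seen. Counts are genes past the threshold, in the order CB1KO against WT on SD, on HFHS, averaged, interaction, diet in WT and diet in CB1KO, where only counts that moved are given and the cause was not tested unless stated.

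Normexp with quantile normalization gave 24 genes on SD, 111 on HFHS (54 shared), 370 averaged (155 shared), 1 for the interaction, and 2 genes and 14 lists for the diet in CB1KO. Quantile normalization gave 23 on SD, 359 averaged (154 shared) and 2 for the diet in CB1KO. The z-scores gave 25 on SD and 3 genes and 16 lists for the diet in CB1KO, and for the diet in WT the median shift of oxidative phosphorylation turned to -0.1912 and that of the tricarboxylic acid cycle to -0.1347. Without a filter there were 135 averaged (128 shared) and 4 for the diet in CB1KO, with a filter on all arrays 7 on SD and 20 for the diet in CB1KO, and with the mean of a gene's probes 3 on SD. A trend with robust variances gave 5 on SD, 106 on HFHS (61 shared) and 1 for the diet in CB1KO. Array weights gave 53, 2006 (68 shared) and 1893 (205 shared) for the genotype, 99 for the diet in WT, 95 genes and 16 lists for the diet in CB1KO, Mstn on HFHS at -1.2208, and a median shift of 0.0423 for oxidative phosphorylation averaged over diets. The replicate block gave 36 on HFHS, 59 averaged (54 shared) and 0 for the diet in CB1KO, and only the groups compared 0 on SD, 43 on HFHS and 0 for the diet in CB1KO, with fewer residual degrees of freedom. Without both arrays of unusual spread there were 236, 193 and 891 for the genotype, 11 for the interaction, 1 and 25 for the diet, 15 lists for the diet in CB1KO, Cnr1 on SD at 0.0245 and oxidative phosphorylation averaged at 0.0406. The SD covariate gave 150, 355 and 1752 for the genotype and 15 genes and 14 lists for the diet in CB1KO. Camera with an estimated correlation and fry's directional test called 0 lists in each of the 6 comparisons. Keeping outlier spots moved none of these.

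Leaving out 1 array at a time gave 0 to 26, 20 to 133, 47 to 617, 0 to 11, 0 to 0 and 0 to 30 genes, and 7 to 23, 7 to 14, 9 to 17, 11 to 15, 9 to 15 and 8 to 15 lists. Cnr1 ranged from -0.5393 to 0.0245 on SD, from -0.4674 to 0.0445 on HFHS (0.0363 without CB1KO_HFHS replicate 2, 0.0185 without CB1KO_HFHS replicate 4) and from -0.3498 to -0.056 averaged. Il6 ranged from 1.482 to 2.7531, from -0.1361 to 0.4045 and from 0.8437 to 1.4793, and Mstn from -0.8981 to -0.3007, from -1.2826 to -0.6865 and from -0.9615 to -0.5921. Arrays of the same replicate number were hardly more alike than others: 8 of 24 such pairs correlated above 0.1 (median 0, against -0.01 for different numbers). This does not exclude an effect of the slide column, which the replicate number follows. Signal over background limits Fgl1, Toporsl, Olfr486 and other dim genes to bounds.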

Other observations

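The macrophage covariate was chosen after the results were seen, and the innervation genes before theirs were. Chrna1 and Cdkn1a (on 1 of its 2 probes), which rise in denervated muscle, were higher in CB1KO, so 12 other genes that respond to loss of innervation were examined. Chrnd (0.76 ± 0.24), Runx1 (0.71 ± 0.19) and Chrnb1 (0.49 ± 0.11) lay higher, while the ubiquitin ligases Fbxo32 (-0.45 ± 0.19) and Trim63 (-0.50 ± 0.21) and the corepressor Dach2 (-0.92 ± 0.49) lay lower, and none passed over all genes. Of the 12, 7 lay above the median gene, with a median shift of 0.0396 (camera p = 0.115, and p = 0.259 with an estimated correlation). A shift of 0.1 or lower had been set to count against the hypothesis. That rule takes every member to rise on loss of innervation, which need not hold for each of them, Dach2 included. Moreover, 3 members were higher and 2 lower at an unadjusted p under 0.05, so a median near 0 decides nothing and the hypothesis stays open.

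Gene lists called in no comparison by camera are given here with their median shift in CB1KO against WT averaged over diets and their smallest adjusted p at the preset correlation over the 6 comparisons. Among myokines (0.12, 0.0595), Ostn, encoding osteocrin, had -1.46 ± 0.35, Igf2 1.34 ± 0.34 and Il15 0.73 ± 0.22, and none passed over all genes. In the myostatin and activin pathway (-0.08, 0.0888), Acvr1b had -0.51 ± 0.14. Nerve and Schwann cell markers (-0.22, 0.0708) lay below the median gene in 12 of 13 cases, for example Prx (-0.72 ± 0.32). Genes of fatty acid synthesis (0.02, 0.234) included Srebf1, a lipogenic transcription factor, at -0.57 ± 0.12 (adjusted p = 0.0517), and cholesterol synthesis (0.06, 0.4) included Fdps at -0.42 ± 0.10. In the endocannabinoid system (0.00, 0.639), Dagla, which makes 2-arachidonoylglycerol, had -0.47 ± 0.18. The heat shock and endoplasmic reticulum list (0.15, 0.214) had Hspa1a higher and Chac1 lower.

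The other lists were antioxidant genes (0.13, 0.0762), mitochondrial unfolded protein and one-carbon stress (0.15, 0.0762), with Psat1 at 1.11 ± 0.26 on 1 of its 2 probes and 0.01 on the other, the circadian clock (0.01, 0.055), glucose use (0.04, 0.251), muscle atrophy (0.07, 0.18), red blood cells (0.22, 0.051), tendon and bone (-0.02, 0.346), brown adipocytes (-0.05, 0.158), epidermis (-0.10, 0.789) and Y chromosome genes (0.05, 0.718). With the macrophage score as a covariate, the fold changes of the 205 genes were a median of 0.967 times those without, and 35 of them passed as the median SE grew from 0.191 to 0.218.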
